A study of Homo sapiens with 28 samples.

How the data were processed

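RNA of the human glioblastoma cell line U-251 MG and of lines derived from it was measured on 28 one-colour (Cy3) Agilent whole-genome oligonucleotide arrays, 1 sample to an array. The authors deposited a scanner file for each array and a table of values for the series. The deposited values are intensity on a linear scale: background-subtracted and detrended within each array by Agilent Feature Extraction, with no normalization between arrays. The value table of the series equalled the processed signal of the scanner files on every array. The headers of the scanner files name 3 versions of that software, 9.5.3.1 on 15 arrays, 10.5.1.1 on 12 and 10.1.1.1 on 1, and the arrays lie on 9 slides with 4 scan days. Of the 6 arrays of the transient comparison, the p53 siRNA array of experiment 3 alone was on slide 9 and on a scan day of its own. The arrays of version 9.5.3.1 were scanned with an extended dynamic range, and the first principal component, 73.7% of the variance, separated the 12 arrays of version 10.5.1.1 from the other 16. Each of the 3 comparisons between arms was made within 1 version, except that the Usi12 lines of the re-expression comparison have version 9.5.3.1 and the sh6 and sh10 lines 10.5.1.1; the clone was a block there. The depletion effects of siRNA and shRNA come from different versions.

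From the files, the log2 of the processed signal was taken and the 75th percentile of each array over non-control probes was subtracted. Probes of 1 sequence ID were averaged, which left 41000 probes. Gene names came from the files and the reference table of human genes: 25398 probes matched by accession, 2510 by symbol and 789 by an older symbol, and 12303 kept the name in the files. For each name the probe with the highest mean over the 28 arrays was used, 30140 names in all, of which 18329 are named genes. Coordinates are those of build hg18 in the headers' design annotation. A probe entered a comparison if it was well above background on at least 3 of its arrays. A value for a probe that was not well above background on any array of 1 arm was turned into a bound, "at least N-fold".

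The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variance), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The comparisons were p53 siRNA against control siRNA (3 arrays each), p53 shRNA clones against scrambled shRNA clones (4 and 3), mutant p53 R273H against empty vector (3 each, with the parent clone as a block), and the difference between the siRNA and shRNA effects. The clone was the replicate in the stable comparison, so the 2 subclones of Usi12 stayed out. A further pair of siRNA arrays and a pair from the scrambled clone scr1 were held out, since the series description counts 3 biological replicates. In 1 sample of the further pair, the labels disagree on which siRNA was used; the title and the source name were followed. To check the pairing, the profile of each array was correlated with those of the other arm after its arm's mean was removed. Arrays of 1 experiment correlated at r = 0.61, 0.44 and 0.39, against at most 0.04 between experiments, and arrays of 1 clone at 0.78, 0.74 and 0.86, against at most 0.08. The transient comparison was nevertheless unblocked as fixed, and the blocked values are given beside it.

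24 gene lists were tested with camera at a correlation between genes of 0.01, and again with an estimated correlation and with fry, with adjustment over the lists of a comparison. They were p53 target genes, reported mutant p53 activated genes, cholesterol synthesis, proteasome subunits, nucleotide synthesis, DNA replication, mitosis, interferon response, NF-kB inflammatory genes, extracellular matrix, mesenchymal and epithelial adhesion, neural stem and glioma markers, markers of astrocytes, neurons and oligodendrocytes, immune and endothelial markers, unfolded protein and amino acid stress, hypoxia and glycolysis, mitochondrial biogenesis and oxidative phosphorylation, antioxidant genes, growth factor receptors and signalling, TGF-beta and BMP response, replication-dependent histones and RNA interference machinery. The samples, tests, lists, a first set of alternatives and the rule for named genes were fixed before the data were examined. The rule names, among others, PPARGC1A and FRMD5; then, in each direction, up to 12 genes past the threshold that moved 1 way in every pair or did not overlap between groups, filled up to 5 with the genes of smallest p; then up to 4 members of each list with the smallest p. Probes without a gene name and genes not above background in both groups were not named by it. Results of some of the genes it names are not reported here.

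The alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, values without scaling, no filter, a filter on every array, the mean over the probes of a gene, a trended and robust variance, the slide as a random block (statmod 1.5.0) or a fixed block, a replicate block, other sets of samples, and leaving out each replicate. Combinations over all 5 siRNA pairs with normexp, with the trended variance or with only probes well above background on all 10 arrays, experiments 1 and 2 alone, and the replicate block with normexp were added after the data were seen. The filter on every array drops genes that fell to background.

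The scripts were tested on simulated data with 200 changed genes. In the transient design (19776 genes), 14.9% of changes of log2 1, 95.5% of 2 and 98.5% of 3 were called. With the replicate block these were 73.1%, 98.5% and 100%. In the stable design (26421 genes) they were 14.9%, 86.6% and 93.9%, and in re-expression (21199 genes) 13.4%, 92.5% and 100%. Over 5 pairs with bright probes (17813 genes) 92.5% of changes of log2 1 were called and 100% of 2 and 3. Unchanged genes called were 11 in the transient design, 19 with the replicate block, 6 in the stable design, 18 in re-expression and 13 over 5 pairs. The simulated noise was drawn from the moderated variance of each gene, which differs less between genes than the measured variance. The shares called may therefore be too high for the data. In the transient comparison PDGFRL, at -2.27 ± 0.21, did not pass (limma adjusted p = 0.0991). Camera found 2 of 2 lists shifted by 0.5 in each design and called 0 of the others. The simulated genes varied independently and the lists held random genes. The simulation therefore cannot show how often lists of correlated genes are called falsely. In the data the estimated correlation was 0.69 for mitosis in the transient comparison. The number of arrays limits the precision. Probe handling and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.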

Results

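The series covers U-251 MG, an established glioblastoma line that carries mutant p53. The p53 protein is a transcription factor that restrains proliferation after DNA damage. Cells of 3 experiments were taken 96 h after transfection with a p53 siRNA (3 arrays) or a scrambled siRNA (3 arrays). A further pair of single U-251 MG arrays and a pair from the scrambled shRNA clone scr1 received the same siRNAs. Stable depletion is represented by 4 clones with a p53 shRNA (sh6, sh10, sh23 and Usi12) and 3 with a scrambled shRNA (scr1, scr2 and scr3), with 2 subclones of Usi12. Clones sh6, sh10 and Usi12 were each also transfected with p53 R273H or with empty vector, 3 arrays per arm. The parental line gave 1 array and its sublines 2. Between 25963 and 29166 of 41000 probes were well above background on the 12 arrays of the later scanner software, and between 33968 and 37190 on the other 16. Differences are in log2 units relative to the 75th percentile of each array, with the standard error, and positive values are higher in the depleted or re-expressing arm.

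The transient comparison asked what depletion of mutant p53 does to the transcriptome within days. Genes of cholesterol synthesis, amino acid stress and the interferon response lay lower as groups, and those of DNA replication, mitosis and the replication-dependent histones higher. No list was called with an estimated correlation between genes or by fry.

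Among single genes, limma called 1 of 19776, a transcript known only as the expressed sequence tag AI948877 (-3.65, adjusted p = 0.0351). It lay at 0.18 and 0.61 in the held-out pairs, so its direction turned there, and it is named here after its values were seen. At an unadjusted p under 0.05 there were 2499 genes. Limma called 2 genes without p53 siRNA replicate 1 and 0 without any other single array. The genes with the smallest p that were higher did not pass: TERF2IP, a telomere-binding protein, lay 3.09-fold higher (1.63 ± 0.23, adjusted p = 0.200), LZTS1 1.90 ± 0.28, COL8A1, a collagen chain, 1.38 ± 0.22 and MAP1LC3A, an autophagy protein, 1.04 ± 0.17, while MC5R lay at least 1.85-fold higher. On the lower side PDGFRL lay at -2.27 ± 0.21 (adjusted p = 0.0991), RAB6B at -2.07 ± 0.21, ELOVL4, which elongates very long fatty acids, at -1.96 ± 0.23 and BCAN, the brain proteoglycan brevican, at -1.99 ± 0.23, with GDPD5 at least 3.60-fold lower. TERF2IP lay at 1.19 and 1.44 in the held-out pairs, PDGFRL at -0.62 and -0.89, and RAB6B at -0.36 and 0.00. LZTS1, COL8A1, MAP1LC3A, ELOVL4 and BCAN kept their direction in both, MC5R lay at -0.94 and 0.46, and GDPD5 at 0.37 and -0.08. PPARGC1A, a coactivator of mitochondrial genes, lay at 0.66 ± 0.31 but turned in the held-out pairs (-0.36 and -0.17). FRMD5 lay at 0.17 ± 0.20, with -0.01 and -0.03 in experiments 1 and 2 and 0.55 in experiment 3. In the held-out pairs FRMD5 lay at -0.20 and -0.08. With the replicate block 13 genes passed, all lower, among them GCNT3 (-3.98 ± 0.21, adjusted p = 0.0359), SLC16A5 (-2.57 ± 0.15) and RAB6B, against 1 without it. In the held-out pairs GCNT3 lay at only -0.58 and -0.80 and SLC16A5 at 0.05 and -0.01, and of the 13, 5 were lower in both and 3 higher in both. GCNT3 and SLC16A5 were chosen after their values were seen.

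The 24 genes of cholesterol synthesis were all lower, with a median of -0.69 (camera adjusted p = 8.15e-08; adjusted p = 0.440 with an estimated correlation). Adjusted over the list alone, 4 of them fell, among them INSIG1, which holds the sterol sensor in check, by 1.57 ± 0.31, MVD by 1.66 ± 0.42 and MSMO1 by 1.77 ± 0.47. In the held-out pairs this list had medians of only -0.02 and -0.18. Of 33 genes of the unfolded protein and amino acid stress responses 30 were lower, with a median of -0.39 (adjusted p = 1.70e-06; adjusted p = 0.440 with an estimated correlation). There ASNS, asparagine synthetase (-1.12), the stress factor DDIT3 (-1.05) and PSAT1 of serine synthesis (-1.09) fell, adjusted over the list alone. The interferon response list had a median of -0.22, with 22 of 35 genes lower (adjusted p = 0.00549; adjusted p = 0.440 with an estimated correlation), and 5 fell adjusted over the list alone, including the antiviral genes MX1 (-1.11), MX2 (-2.47) and ISG20 (-1.40). Without control siRNA replicate 2 the interferon call was lost (adjusted p = 0.143). The interferon medians in the held-out pairs were 0.05 and -0.33. Proteasome subunits had a median of -0.17, with 27 of 31 lower (adjusted p = 0.0466; adjusted p = 0.486 with an estimated correlation), and the call was lost with the replicate block (adjusted p = 0.0759) and without control siRNA replicate 1 or 2 or p53 siRNA replicate 1 or 3 (adjusted p from 0.0557 to 0.260).

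Replication-dependent histones, which package newly made DNA, were higher in 18 of 19 genes with a median of 0.61 (adjusted p = 2.42e-08; adjusted p = 0.440 with an estimated correlation), as in H4C8 (0.72 ± 0.18) and H1-2 (0.87 ± 0.23). Their medians in the 5 pairs were 0.65, 0.31, 0.95, 0.45 and 0.62. Mitotic genes were higher in 39 of 40 with a median of 0.48 (adjusted p = 2.42e-08; adjusted p = 0.486 with an estimated correlation), as in MKI67, the proliferation marker (0.97 ± 0.34), and BUB1B (0.78 ± 0.23). DNA replication genes were higher in 35 of 37 with a median of 0.39 (adjusted p = 8.15e-08; adjusted p = 0.440 with an estimated correlation), as in LIG1 (0.67 ± 0.18) and the helicase subunit MCM2 (0.62 ± 0.20). In none of these 3 lists did a member pass, adjusted over the list alone. Extracellular matrix genes had a median of 0.23, with 28 of 38 higher (adjusted p = 0.00166; adjusted p = 0.440 with an estimated correlation), and COL8A1, DCN (1.21) and TIMP3 (1.25) rose adjusted over the list alone. TGF-beta and BMP response genes had a median of 0.52, with 14 of 23 higher (adjusted p = 0.00326; adjusted p = 0.440 with an estimated correlation), where the ligands BMP4 (1.21) and TGFB3 (1.07) rose adjusted over the list alone, but this call was lost over all 5 pairs (median 0.13, adjusted p = 0.153). Neural stem and glioma markers had a median of 0.49, with 14 of 19 higher (adjusted p = 0.00855; adjusted p = 0.486 with an estimated correlation); SOX4 (1.17) rose adjusted over the list alone and SOX2 lay at 1.17 ± 0.32.

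The list of p53 target genes was not called, with a median of 0.08 and 26 of 41 higher (adjusted p = 0.173); ACTA2 lay at 1.21, SESN1 at 0.67 and PLK2 at -0.75. Reported mutant p53 activated genes had 13 of 28 higher (adjusted p = 0.540), with ASNS the 1 member that fell adjusted over the list alone. Also not called were RNA interference machinery (10 of 15 higher, adjusted p = 0.0958), where TNRC6C, a partner of Argonaute, rose adjusted over the list alone (1.28 ± 0.27), and mitochondrial biogenesis and oxidative phosphorylation (23 of 34 higher, 0.349). Nor were nucleotide synthesis (11 of 22 higher, 0.409), NF-kB inflammatory genes (8 of 25, 0.344), adhesion genes (13 of 25, 0.540), hypoxia and glycolysis (19 of 34, 0.969), antioxidant genes (5 of 24, 0.349) or growth factor signalling (17 of 33, 0.874). Markers of other cell types were not called either: astrocytes (9 of 13 higher, 0.196), neurons (1 of 11, 0.184), oligodendrocytes (2 of 4, 0.606), and immune and endothelial cells (2 of 9, 0.540). Of the 586 list members tested, limma called 0 over all genes and 98 had an unadjusted p under 0.05, and fry called 0 lists. Slide 6, the 1 slide with both arms, holds 1 p53 siRNA array of experiment 1 and 1 control array of experiment 2, so its values compare single arrays of different experiments. The medians there were 0.73 for histones, 0.25 for mitosis, 0.03 for DNA replication, -0.15 for cholesterol synthesis, -0.36 for interferon response, -0.09 for amino acid stress, -0.10 for proteasome subunits, -0.06 for extracellular matrix, 0.43 for TGF-beta response and 0.46 for neural stem markers.

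**Figure D1:**
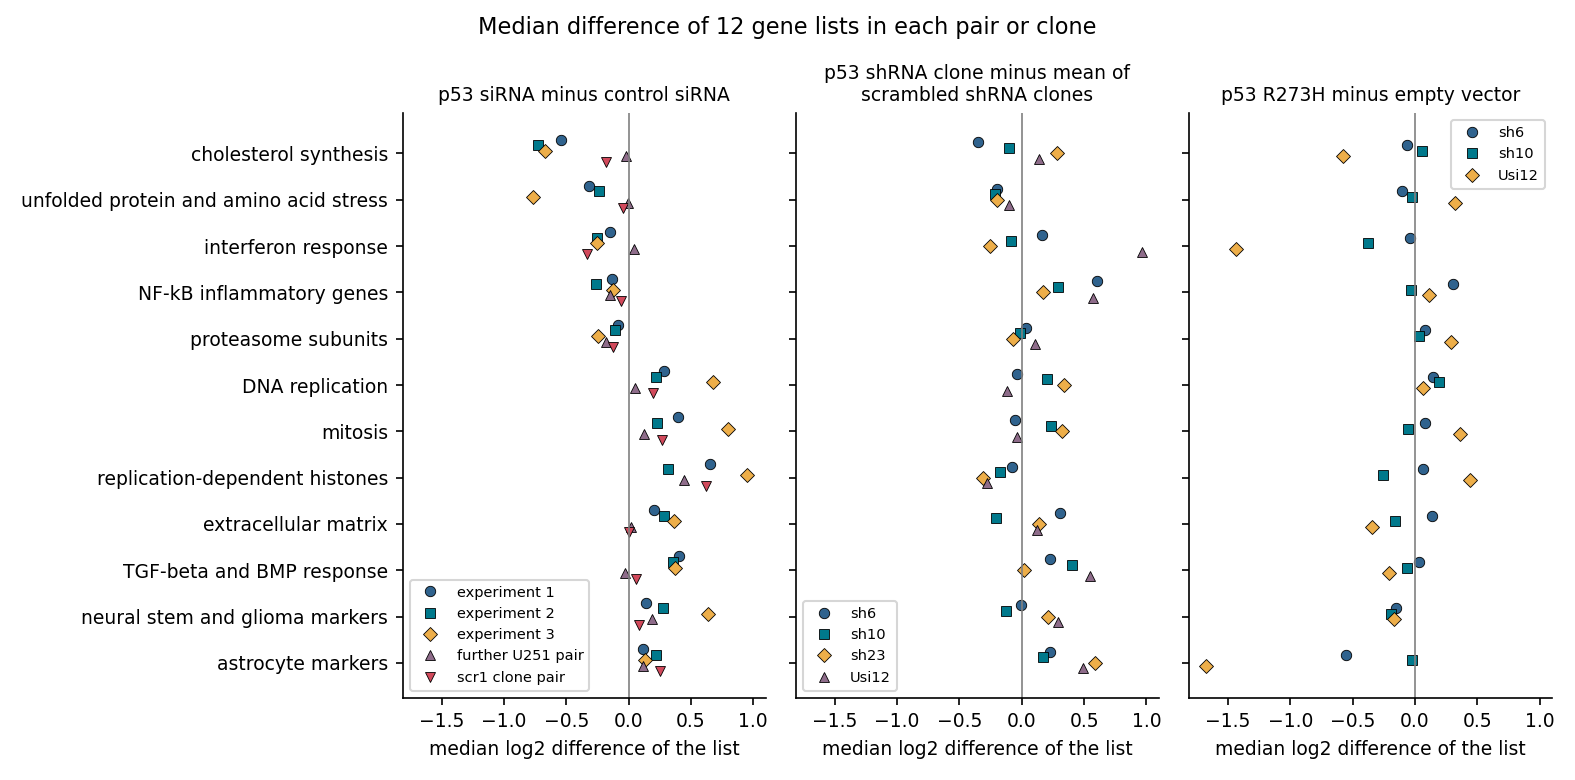
Median log2 difference of 12 gene lists in each siRNA pair, each p53 shRNA clone against the mean of the scrambled clones, and each clone with p53 R273H against empty vector; each point is 1 pair or clone. Histone medians are positive in all 5 siRNA pairs (0.31 to 0.95) and negative in all 4 shRNA clones (-0.08 to -0.31).

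The held-out pairs asked whether these differences recur. Of the 100 genes with the smallest p, 83 had the same sign in the further U-251 MG pair (95% Clopper-Pearson interval 74.2% to 89.8%) and 82 in the scr1 pair (73.1% to 89.0%). These intervals treat the 100 genes as independent, which they are not, and do not measure the spread between pairs. The median difference in the direction of the experiments was 0.44 and 0.46 there, against 1.54 in the experiments. Over all genes, which are not independent replicates, 61.9% and 61.7% had the same sign. The list medians in these pairs were 0.02 and 0.01 for extracellular matrix and -0.03 and 0.06 for TGF-beta response. They were 0.12 and 0.27 for mitosis, 0.05 and 0.20 for DNA replication and 0.19 and 0.09 for neural stem markers. Proteasome subunits had medians of -0.18 and -0.13.

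Over all 5 pairs, 5406 of 19770 genes (27.3%) moved 1 way in every pair, 2814 higher and 2592 lower. The share would be 6.25% if the pairs were independent and either direction equally likely for each gene, which was not tested. At least 2-fold lower in every pair were, among others, CTSC, a lysosomal protease (-1.59 over the 5 pairs), CPA4 (-1.65), the growth factor FGF1 (-1.47) and POLR1H of RNA polymerase I (-1.35). At least 2-fold higher in every pair were 7 genes: TERF2IP (1.50), EHD1, which recycles endosomes (1.51), PLEKHS1 (2.05), NRTN, the neurotrophic ligand neurturin (1.49), the serotonin receptor HTR2A (2.24), SOX2-OT (1.67) and STON1-GTF2A1L (1.30). These genes were chosen after their values were seen. In the fit fixed beforehand, with the pair as a replicate block, limma called 0 of 26187 genes, with 5290 at an unadjusted p under 0.05.

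With only probes well above background on all 10 arrays, a filter added after the data were seen, limma called 1660 of 17813 genes over the 5 pairs, 843 higher and 817 lower. In that fit 13 of 19 histone genes rose, among them H2AC6 (0.81 ± 0.12, adjusted p = 0.0161), H2BC12 (0.66 ± 0.10) and H4C8 (0.74 ± 0.11), and 8 of 24 cholesterol genes fell, among them MSMO1 (-1.31 ± 0.23) and SC5D (-0.61 ± 0.12). Of DNA replication genes 6 of 37 rose, with CCNE1, the S-phase cyclin, at 0.56 ± 0.10, and of mitotic genes 5 of 40, with the phosphatase CDC25B at 0.66 ± 0.10. Among p53 target genes 5 of 40 rose and 2 fell. BTG2, an inhibitor of proliferation, rose (adjusted p = 0.0118, at 1.15 ± 0.59 over experiments 1 to 3 alone) and ACTA2 rose by 0.94 ± 0.16, while PLK2 fell by 0.83 ± 0.15. The matrix list had 7 of 37 higher, such as DCN (1.01 ± 0.17) and 1 lower, and neural stem markers 4 of 18 higher, such as SOX4 (0.91 ± 0.15) and SOX2 (0.95 ± 0.18). In growth factor signalling 5 of 33 fell, including the ligand PDGFA (-0.96 ± 0.14) and the receptor PDGFRB (-1.19 ± 0.21), and 1 rose. MYC fell by 0.73 ± 0.11 and PDGFRB fell among the 28 reported mutant p53 activated genes, where 2 others rose. Interferon response had 4 of 34 lower, such as RIGI, a sensor of viral RNA (-0.60 ± 0.12), amino acid stress 3 of 33 lower, such as PSAT1 (-1.01 ± 0.15), and RNA interference machinery 2 of 15 higher, TNRC6C (1.15 ± 0.18) and DICER1 (0.59 ± 0.12). None of 33 mitochondrial genes passed.

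**Figure D2:**
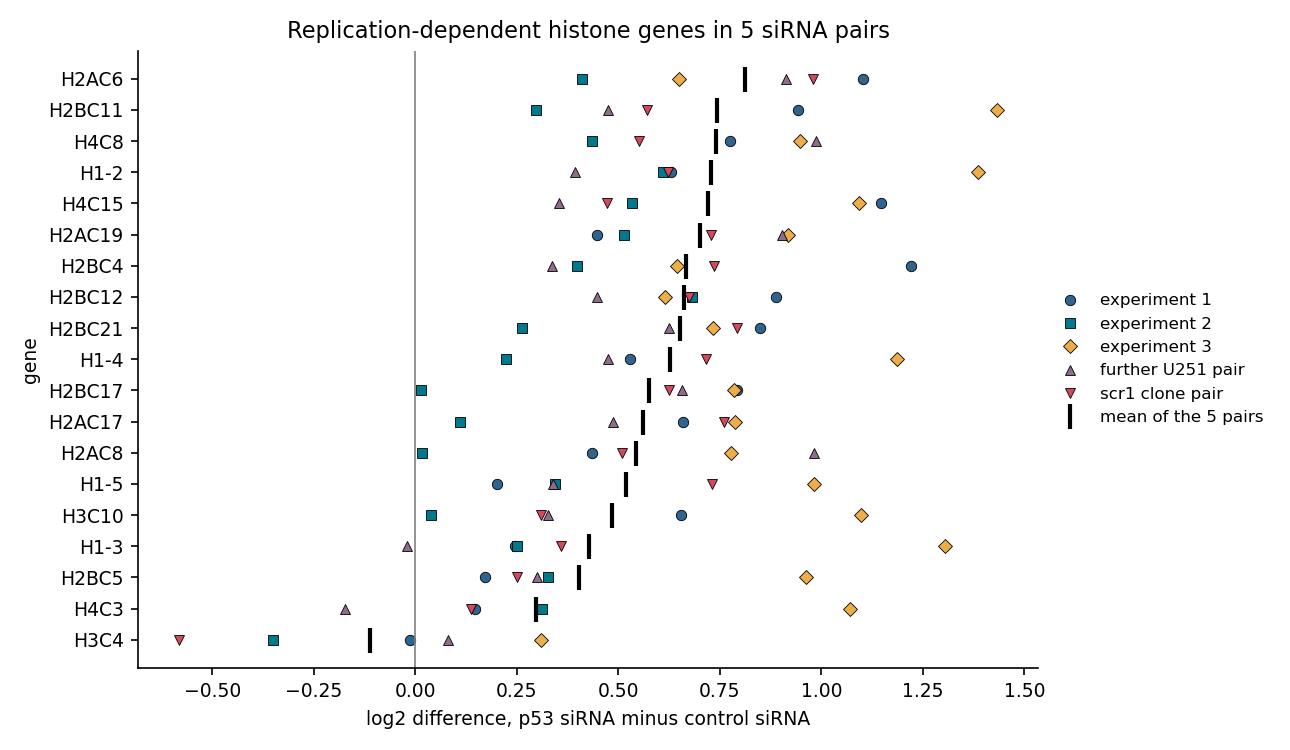
Log2 difference (p53 siRNA minus control siRNA) of 19 replication-dependent histone genes in each of the 5 siRNA pairs; points are pairs and black bars their mean. All 5 pairs are positive for 16 of the genes, and 13 rose in the fit of bright probes.

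The stable comparison asked what lasting depletion does in cloned lines. NF-kB inflammatory genes lay higher as a group, and stress response and histone genes lower. No list was called with an estimated correlation between genes or by fry. SRSF12, a splicing factor, lay at least 2.21-fold higher (adjusted p = 0.147) and CRABP1, a carrier of retinoic acid, at -2.20 ± 0.42 (adjusted p = 0.384); neither passed.

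Limma called 0 of 26421 genes in the stable comparison, with 2146 at an unadjusted p under 0.05. The genes of smallest p that lay higher were, beside SRSF12, RIMKLA (1.13 ± 0.15), LIX1 (1.24 ± 0.18), MCF2, a guanine nucleotide exchange factor (at least 1.68-fold), and the TNF receptor TNFRSF1B (at least 1.47-fold). Lower lay WDTC1 (-1.68 ± 0.30), NUB1, which targets NEDD8 for breakdown (-1.25 ± 0.23), CT47A11 (-1.06 ± 0.21) and DCANP1 (-0.94 ± 0.19). PPARGC1A lay at 0.77 ± 0.47 and FRMD5 at 0.33 ± 0.54. NF-kB inflammatory genes were higher in 25 of 31 with a median of 0.43 (camera adjusted p = 0.0232; adjusted p = 0.684 with an estimated correlation), as in the cytokines IL1B (0.99 ± 0.27) and IL1A (1.09 ± 0.36) and the feedback inhibitor TNFAIP3 (0.85 ± 0.24), whereas CXCL3 lay at -1.82 ± 0.47. The NF-kB call was lost without scr2 (adjusted p = 0.138) and without sh10 (adjusted p = 0.212). Unfolded protein and amino acid stress genes were lower in 24 of 31 with a median of -0.17 (adjusted p = 9.65e-04; adjusted p = 0.154 with an estimated correlation), as in CRELD2 (-0.54 ± 0.21), a call lost with quantile normalization (adjusted p = 0.302) and with normexp (adjusted p = 0.309). Histones were lower in 17 of 20 with a median of -0.21 (adjusted p = 5.40e-05; adjusted p = 0.228 with an estimated correlation), as in the linker histone H1-4 (-0.52 ± 0.19). Interferon response genes had a median of 0.20, but 0.97 in Usi12 and -0.25 in sh23, and were not called. The 21 lists not called had adjusted p between 0.170 and 0.924, among them p53 target genes (24 of 43 higher, 0.806), where the death receptor TNFRSF10B lay at 0.68 ± 0.22 and GADD45A at 0.70 ± 0.24. Adjusted over the list alone, 0 members of any list passed; 39 of 639 members had an unadjusted p under 0.05, and fry called 0 lists. The median of all genes lay at 0.09, so several uncalled lists, the p53 target genes among them, had a positive median where camera gave a downward direction. Slide 2, the 1 slide with both arms, holds 1 p53 shRNA clone, sh10, beside scr1 and scr3; the medians there were 0.33 for NF-kB genes, -0.25 for stress genes and -0.26 for histones. Without sh10, limma called 155 genes, 97 higher and 58 lower, and without scr2 it called 2. Without sh10 no slide holds both arms, so arm and slide cannot be told apart in those 155.

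The re-expression comparison asked whether mutant p53 reverses the effects of depletion. Antiviral genes of the interferon response and astrocyte markers lay lower as groups with p53 R273H, most of all in Usi12, and genes of DNA replication, nucleotide synthesis, mitosis and the proteasome slightly higher. No list was called with an estimated correlation between genes or by fry.

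Limma called 0 of 21199 genes for re-expression, with 823 at an unadjusted p under 0.05 (30 without the clone block). None of the following passed, each with an adjusted p of 0.910. TPH2, which makes serotonin (0.98 ± 0.19), SEC14L4 (0.97 ± 0.20), the signalling scaffold CARD10 (0.86 ± 0.19) and LHFPL4 (0.80 ± 0.19) lay higher. PLEKHS1 (-1.68 ± 0.22), PSG4 (-1.35 ± 0.20), SLC2A13, a myo-inositol transporter (-1.30 ± 0.20), the collagen COL14A1 (-1.50 ± 0.24), CT55 (-1.50 ± 0.24) and PPARGC1A (-0.84 ± 0.21) lay lower, and FRMD5 lay at 0.54 ± 0.35. The interferon response was lower in 31 of 36 genes with a median of -0.62 (camera adjusted p = 1.79e-08; adjusted p = 0.803 with an estimated correlation), as in MX2 (-1.81 ± 0.37) and MX1 (-2.08 ± 0.72). Its median was -0.04 in sh6, -0.38 in sh10 and -1.43 in Usi12. Astrocyte markers were lower in all 11 genes with a median of -0.76 (adjusted p = 3.64e-04; adjusted p = 0.803 with an estimated correlation), as in GFAP, the astrocyte filament protein (-1.01 ± 0.34), and SPARCL1 (-2.22 ± 0.77), with -0.55 in sh6, -0.02 in sh10 and -1.68 in Usi12. DNA replication genes were higher in 32 of 37 (median 0.14, adjusted p = 0.00385), nucleotide synthesis in 19 of 22 (0.11, adjusted p = 0.00593), proteasome subunits in 27 of 31 (0.13, adjusted p = 0.00643) and mitotic genes in 27 of 40 (0.14, adjusted p = 0.0474). For each of these 4 lists adjusted p = 0.803 with an estimated correlation. All 4 calls were lost with quantile normalization (adjusted p = 0.0519, 0.109, 0.256 and 0.355), and those of the proteasome (0.0684) and mitosis (0.243) also with normexp. The mitosis call was lost as well with no filter (0.0515) and with the filter on every array (0.0516). DNA replication and nucleotide synthesis were not called without sh6 (adjusted p = 0.0943 in both), mitosis not without sh6 (0.102) or Usi12 (0.880, median -0.00748), and the proteasome not without Usi12 (0.606). The other 18 lists had adjusted p between 0.0603 and 0.946, 0 members passed adjusted over the list alone, 33 of 600 had an unadjusted p under 0.05, and fry called 0 lists. Slides 7 and 8 each hold 1 array per arm, but of different clones: the interferon median was -0.09 and -0.18 there, the astrocyte median 0.47 and -0.76, mitosis 0.40 and -0.33, DNA replication 0.36 and 0.05, nucleotide synthesis 0.39 and -0.03, and the proteasome 0.15 and -0.04.

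The last comparison asked whether transient and stable depletion move the same genes. Histones lay 0.85 higher in the siRNA effect than in the shRNA effect and cholesterol genes -0.65, while the median of all genes differed by -0.13 (-0.02 after quantile normalization). Limma called 0 of 26590 genes for this difference, with 2570 at an unadjusted p under 0.05, and 15 after quantile normalization. Across genes, which are not independent replicates, the transient and stable differences correlated at a Spearman coefficient of 0.131, transient and re-expression at 0.078, and stable and re-expression at -0.003. Without 1 array these ranged from 0.0553 to 0.161, from -0.00375 to 0.162 and from -0.125 to 0.110. Of genes with an unadjusted p under 0.05 in both depletions, 92 moved the same way, where 70.7 would by independence, and 49 opposite ways, where 73.3 would. Between stable depletion and re-expression 52 moved opposite ways, where 29.1 would, and 16 the same way, where 21.6 would. Between transient depletion and re-expression 81 moved the same way, where 43.0 would, and 56 opposite ways, where 38.4 would, so that most shared genes there did not run against depletion. Both directions exceeded independence there, so independence is no firm baseline for these counts. The 823 of 21199 genes under 0.05 in re-expression are also a smaller share than chance alone would give. The counts therefore do not decide whether re-expression reverses depletion.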

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

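The tests on scan batches and on the stable clones over the genes called in 5 pairs were chosen after the results were seen, as was the 5-pair fit of bright probes they use.

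In 8 gene lists the effect of p53 siRNA differed from that of p53 shRNA by a camera test of the difference itself, where the median of all genes lay at -0.13. Replication-dependent histones differed by 0.85 (adjusted p = 1.43e-15; adjusted p = 0.0781 with an estimated correlation), and they were the 1 list that fry called (adjusted p = 0.0284). Cholesterol synthesis differed by -0.65 (adjusted p = 0.00265), DNA replication by 0.34 (adjusted p = 1.90e-06), mitosis by 0.36 (adjusted p = 6.10e-07) and extracellular matrix by 0.30 (adjusted p = 0.00368), each with adjusted p = 0.488 with an estimated correlation. Neural stem and glioma markers differed by 0.16 (adjusted p = 0.0416; adjusted p = 0.488 with an estimated correlation). Immune and endothelial markers differed by -0.66 (adjusted p = 0.0416; adjusted p = 0.438 with an estimated correlation), and RNA interference machinery by 0.0275 (adjusted p = 0.0416; adjusted p = 0.316 with an estimated correlation). The 2 effects come from different versions of the scanner software, but the held-out siRNA pairs share that of the stable clones. There the histone medians were 0.45 and 0.62, against -0.08 to -0.31 in the 4 p53 shRNA clones, which argues against the version as the whole cause of the histone difference. In the other 7 lists the held-out medians lay within the range of the 4 clones, so an effect of the version stays open there.

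In the 100 genes of smallest p, the p53 siRNA differences mostly kept their direction in the held-out pairs. These pairs share the scan batch of the stable clones. A slide or scan batch of the 6 arrays as the whole cause is argued against by the share of the same sign there, at least 82% of the 100 genes. The genes are not independent and each held-out pair is a single pair, so no firm interval can be set on that share. Among the 6, the p53 siRNA array of experiment 3 stood apart, alone on slide 9 and on a scan day of its own; without it the shares were 77% and 80%. The shares were lower, under the bound set for this test, without p53 siRNA replicate 1 (72.7% in both pairs) and, in the further pair, without scaling (67%), so the argument is weaker there. An effect of p53 depletion that acts alike in the stable clones is argued against, for these genes alone, by the 1660 genes called in 5 pairs. The stable difference projected on their effects with a slope of 0.00193 (SE 0.114, exact p = 0.971), and 838 of 1651 had the same sign, 50.8%. Across all genes the transient and stable differences correlated at a Spearman coefficient of 0.131. Of genes with an unadjusted p under 0.05 in both, 92 moved the same way, where 70.7 would by independence, and 49 opposite ways, where 73.3 would. Over the 100 genes of smallest p the score of the stable clones was 0.055 of that of the held-out pairs (SE 0.213), an interval that does not decide. Effects of the siRNA outside its target and adaptation of the clones were not tested and stay open; the 10 splits of the 6 arrays are too few for a share under 0.05, and 2 gave at least 1 gene, the real value and the highest other both being 1.

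In 4 of 25 genes and in 0 of 24 list medians tested, where chance gives about 1 in 20, 1 p53 shRNA clone lay far from the other 3. Clone sh6 was the distant one in RIMKLA (gap over range 0.895, at 0.89 against the scrambled clones) and in H1-1 (0.910, at -1.02). Clone sh10 was the distant one in TNFRSF1B (0.920, at 0.94) and in WDTC1 (0.835, at -1.01).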

How the results depend on the processing

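The fits over 5 pairs with normexp, a trended variance or bright probes, the fits of experiments 1 and 2, and the replicate block with normexp were chosen after the results were seen.

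For the 6 arrays of transient depletion the count of 1 gene became 0 with normexp, with no filter, with the filter on every array, with the trended variance and with the slide as a fixed block. It became 793 with the slide as a random block, 13 with the replicate block and 317 with that block and normexp. It was 0 over 4 pairs with or without the block, 0 in experiments 1 and 2 with or without it, and 0 over 5 pairs with the block. Over 5 pairs with the block it was 1371 with normexp, 1498 with the trended variance and 1660 with bright probes. Leaving out 1 array gave 0 to 2, with 2 without p53 siRNA replicate 1. In stable depletion leaving out 1 clone gave 0 to 155 genes (2 without scr2 and 155 without sh10, where no slide holds both arms) and every other alternative 0. In re-expression every alternative gave 0. For the difference of the effects quantile normalization gave 15 and the filter on every array 1, and leaving out 1 array gave 0 to 12, with 12 without control siRNA replicate 2, 7 without replicate 1, and 1 without any of the p53 siRNA arrays or scr2. The cause was not tested, except for the 5 pairs.

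The Spearman coefficient of transient and stable was 0.0109 with no filter. The share of the same sign in the further pair was 92% with normexp and 67% without scaling, in the scr1 pair 89% with quantile normalization and 97% with normexp, and 72.7% in both without p53 siRNA replicate 1, up to 85% and 88%. Without 1 array the coefficient of transient and stable ranged from 0.0553 to 0.161, that of transient and re-expression from -0.00375 to 0.162 and that of stable and re-expression from -0.125 to 0.110.

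The number of lists called in transient depletion, 10, was 2 with the slide as a fixed block, 0 with an estimated correlation, 0 with fry, and 8 to 11 without 1 array. In stable depletion, 3 became 6 with quantile normalization, 6 with normexp, 8 with the slide as a fixed block, 6 with Usi12 and its subclones averaged, 13 with the parental line and sublines as controls (where the median of all genes moved to 0.22), 0 with an estimated correlation and 0 with fry, and 2 to 9 without 1 clone (9 without scr3, 6 without scr2 or sh6, 5 without sh23). Mitosis, mitochondrial, growth factor and TGF-beta lists were newly called higher with both quantile normalization and normexp. In re-expression, 6 became 4 with quantile normalization, 7 with normexp, 11 with the parent clones added (median of all genes -0.17), 0 with an estimated correlation and 0 with fry, and 5 to 10 without 1 clone (10 without sh10). Cholesterol synthesis and antioxidant genes were newly called lower there with quantile normalization (adjusted p = 0.0209 in both) and with normexp (adjusted p = 0.00363 in both). The cause was not tested.

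With the slide as a fixed block the values rest on 1 slide with both arms: in transient depletion on 1 array per arm, of different experiments, and in stable depletion on sh10 against scr1 and scr3, lone samples being assumed to vary like the others. These values reversed. With that block the DNA replication list was directed down by its test (median 0.0267), the extracellular matrix list had a median of -0.0559, HERPUD1 in transient depletion lay at 0.0389 and H1-5 in stable depletion at 0.18. FRMD5, transient depletion, lay at -0.0208 in experiments 1 and 2, with or without the block. In stable depletion, with the parental line and sublines as controls, FRMD5 lay at -0.29, CRABP1 at 0.14, CT47A11 at 0.11, DCANP1 at 1.25 and H1-1 at 0.13. CT47A11 lay at 0.0843 as the mean over its probes, and FRMD5 at -0.0897 to 0.766 without 1 clone. In re-expression LHFPL4 lay at -0.0907 with the parent clones added, and the mitosis list had a median of -0.00748 without replicate 12, clone Usi12, though its test still pointed up. The cause was not tested. Of the other values for named genes and called lists, all kept their direction, for lists that of the test: for genes, 1117 of 1280 in transient depletion, 428 of 442 in stable depletion and 447 of 448 in re-expression also kept their side of the threshold, and for lists 216 of 260, 47 of 60 and 63 of 90. The slide blocks could not be fitted for re-expression.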

Other observations

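The test of scaling on the 5-pair count and the comparison of siRNA pairs with re-expression clones were chosen after the results were seen.

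PLEKHS1 and NRTN, the ligand neurturin, were at least 2-fold higher in all 5 pairs with p53 siRNA and at least 2-fold lower in all 3 clones with p53 R273H. PLEKHS1 lay at 1.32, 2.24, 4.02, 1.34 and 1.35 with siRNA, and at -1.64, -1.36 and -2.05 in sh6, sh10 and Usi12 with p53 R273H. NRTN lay at 1.09, 1.47, 2.43, 1.07 and 1.41, and at -1.47, -1.29 and -3.62. Of 19547 genes, 18 reached 2-fold 1 way in all siRNA pairs and 16 in all re-expression clones, so that 0.0147 would share both by independence, without regard to how noisy a gene is. In the p53 shRNA clones PLEKHS1 lay at -0.64 ± 1.05 and NRTN at 0.18 ± 0.37, neither past the threshold, and PLEKHS1 had an SD of 1.77 among the scrambled clones. Of genes that moved 1 way in all 5 pairs and 1 way in all 3 clones, 771 moved opposite ways, where 680 would by independence, and 691 the same way, where 678 would. At an unadjusted p under 0.05 in both, the balance was the other way: 81 moved the same way, where 43.0 would, and 56 opposite ways, where 38.4 would, and 52.2% of all genes had the same sign.

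The count over 5 pairs depended on background correction, 0 with the processed signal and 1371 with normexp. Scaling between arrays as the cause is argued against by the quantile-normalised processed signal, which gave 0% of the calls of normexp. Noise of dim probes may contribute: on probes well above background the processed signal gave 93.8% of the calls of normexp, and with a trended and robust variance 132%, so that a single prior variance for dim and bright probes may contribute as well. Of 3 equal groups of genes by brightness, the dimmest had a median residual SD of 0.489 with the processed signal and 0.130 with normexp. The 16 swaps of arms within pairs are too few for the share to fall under 0.05; the real count with normexp was 1371, and the highest other 0.

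Chance cannot be excluded for the 2146 genes at an unadjusted p under 0.05 in stable depletion: 8 of 35 splits of the 7 clones gave as many, with a highest of 4025. That split, of sh10 and the scrambled clones against sh6, sh23 and Usi12, called 324 genes, which points to a structure of the clones in which sh10 goes with the scrambled clones. The split differs from the real grouping only in sh10, and the cause was not tested. For re-expression the 4 swaps are too few for a share under 0.05; the real count was 823 and the highest other 677.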
